A study of Homo sapiens with 5 samples.

How the data were processed

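Peak lists from 5 libraries were analysed, 1 for each of the CUT&Tag libraries of HepG2 cells described in the labels. Per the labels' protocols, cells on concanavalin A beads were incubated with a primary and a secondary antibody, then with a transposase fused to protein A/G, and the tagged DNA was amplified with an Illumina index kit. The design text names cells stably expressing Flag-tagged ENL, profiled with Flag or H3K9bhb antibodies. Whether the H3K9ac and H3K9cr libraries came from those cells is not given in the sources used here. Groups were taken from the sample titles.

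FastQC, Bowtie2, MACS2, deepTools and the build hg38 are named, without versions or parameters, per the submitters' processing notes. The deposited lists have the MACS2 narrowPeak layout, with 1 list per library. The control library, duplicate removal, mapping filters, transposase offset and read totals are not given in the sources used here. The deposited fold is the ratio of the summit signal to the caller's background estimate. The deposited p and q columns are −log10 values, and the deposited score is 10 times the −log10 q cut to a whole number in at least 99.97% of the lines of each list. The deposited interval positions and the deposited summit offsets are in base pairs. The smallest deposited −log10 q was 2.05 in wild type ENL, 2.04 in Y78A, 2.02 in H3K9bhb, 1.31 in H3K9ac and 1.34 in H3K9cr, so the lists were not cut at the same threshold. Peak names inside the lists also differ in form between the first 3 libraries and the last 2, and those of the H3K9ac list begin with ENL1. The group was taken from the label in each case. Looser thresholds lengthen a list and raise the share of other peaks it overlaps, and a transposase also favours open chromatin, so an overlap does not by itself separate a mark from accessibility.

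Peaks on the 24 standard chromosomes were used (11394, 5422, 31493, 9176 and 3852 of 12033, 5797, 33213, 9660 and 4148 lines in wild type ENL, Y78A, H3K9ac, H3K9bhb and H3K9cr), and no interval occurred more than once. For 99.98% or more of the peaks of each list, within a relative tolerance of 3e-05, the deposited fold and −log10 p were reproduced by a whole number of summit fragments and a Poisson background, with 1 added to both in the fold. The median summit held 23 fragments in wild type ENL, 21 in Y78A, 33 in H3K9ac, 21 in H3K9bhb and 22 in H3K9cr. The most frequent recovered background of each list served as a measure of relative depth. It may also depend on call settings, which are not given. Folds were used only within a list, to describe, rank and divide its peaks.

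Overlap required at least 1 bp. Shares have 95% Wilson intervals and differences have Newcombe intervals, and neither includes variation between cultures. For wild type minus Y78A shares, the Newcombe interval takes the lists as independent, although many of their peaks lie at the same sites. Chance overlap was the mean of 100 placements of the second list within its chromosomes (bedtools 2.31.1 shuffle). Equal-length lists took the 3852 peaks with the highest −log10 p from each library. Genes were the 20037 protein-coding genes of RefSeq on GRCh38, the assembly also named hg38. That table gives no strand, so the promoter windows fixed before the data were examined were replaced by windows of 1 kb around both ends of a gene, and a peak there can belong to the 3′ end or to a neighbour. A peak counted for a gene when it overlapped the window, and a peak counted as a gene-end peak when its summit lay in one. A gene counted as recovered in Y78A when either end had a Y78A peak.

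The 12 gene lists (462 genes, all matched by symbol) were fixed before the data were examined: liver secreted proteins, liver transcription factors, fatty acid oxidation and ketone bodies, fasting and gluconeogenesis, cholesterol and lipid synthesis, ribosomal proteins, elongation complexes, leukaemia ENL targets, lysine acylation enzymes and readers, cell cycle, replication-dependent histones and genes of other tissues. Each was set against 10000 random lists of protein-coding genes, of H3K9ac genes or of wild type ENL genes. Against H3K9ac or wild type ENL genes, only the list members with that peak at a gene end were counted, beside random lists of their number. Named genes followed a rule on the authors' fold at the strongest gene-end peak. They were the 10 highest wild type genes without Y78A and the 10 with it, the 5 highest Y78A genes without wild type, the 5 highest H3K9bhb genes without H3K9ac, the 5 highest H3K9bhb genes with wild type ENL but not Y78A, and up to 4 members of each list. The 3 strongest peaks of each library were named too. Genes joined by readthrough were skipped. A list member that the rule named is not reported here.

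On simulated data the overlap code found 100% of planted overlaps among 11394 peaks, with a difference of 0 peaks from bedtools. The fragment recovery returned the right whole number for 100% of 2000 simulated peaks, and called 0% of 2000 scaled values whole. Alternatives were other overlap rules, stricter and equal thresholds, equal list lengths, other gene windows and restrictions by position. No p-value was computed, since no group has more than 1 library. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.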

Results

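Peak lists from 5 CUT&Tag libraries of HepG2 cells, a human liver cancer line, were compared to ask whether ENL occupies chromatin marked by β-hydroxybutyrylation of histone H3 at lysine 9 (H3K9bhb). ENL, the product of MLLT1, is a component of transcription elongation complexes and reads acylated lysines through its YEATS domain. The Y78A substitution replaces a tyrosine of the acyl-lysine pocket with alanine. CUT&Tag directs a transposase to antibody-bound chromatin, so a peak marks a place with more tagged fragments than the local background. The libraries were Flag-ENL wild type, Flag-ENL Y78A, H3K9ac (acetylation), H3K9bhb and H3K9cr (crotonylation), with 1 library per group. No difference between libraries therefore had a replicate check, and all intervals are 95% intervals that cover counting error only.

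H3K9ac had the most peaks and H3K9cr the fewest. The standard chromosomes held 31493 H3K9ac peaks over 19.1 Mb, 11394 wild type ENL peaks over 4.99 Mb, 9176 H3K9bhb peaks over 3.70 Mb, 5422 Y78A peaks over 2.10 Mb and 3852 H3K9cr peaks over 1.39 Mb. H3K9ac peaks were also the widest, with a median of 437 bp, against 384 bp for wild type ENL, 355 bp for H3K9bhb, 336.5 bp for Y78A and 307 bp for H3K9cr. Wild type ENL, Y78A and H3K9bhb peaks lay at protein-coding gene ends at similar rates. Their summits were within 1 kb of a gene end in 43.0%, 44.3% and 43.0% of cases, while H3K9ac reached 36.6% and H3K9cr 19.1%. H3K9cr peaks lay more than 100 kb from any protein-coding gene in 25.9% of cases, against 4.80% of H3K9ac peaks. Read totals are unknown. The most frequent background level recovered from the deposited values rises with depth and may also depend on call settings. It was 0.841 times the wild type level in Y78A, 0.937 times in H3K9bhb, 1.60 times in H3K9cr and 1.72 times in H3K9ac.

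To learn which ENL sites were also occupied by the substituted protein, the wild type and Y78A lists were overlapped. Y78A had fewer peaks, and most of them were wild type sites. Of 11394 wild type peaks, 4892 were overlapped by a Y78A peak (42.9%, interval 42.0 to 43.8), whereas 4952 of 5422 Y78A peaks were overlapped by a wild type peak (91.3%, interval 90.6 to 92.1). Over 100 random placements these shares averaged 0.186% and 0.392%. Recovery rose with the p of the wild type peak. In 4 equal groups of wild type peaks ranked by p, from weakest to strongest, Y78A recovered 10.1%, 21.5%, 51.8% and 88.3% of wild type peaks. Ranked by fold, the groups gave 30.2%, 29.9%, 42.2% and 69.5%. With every list limited to its 3852 strongest peaks, 70.6% of wild type peaks (interval 69.2 to 72.1) were overlapped by Y78A. That cut changes list length and peak strength together, so the rise cannot be put down to either alone.

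At gene ends, 5734 of 20037 protein-coding genes had a wild type ENL peak and 2933 had a Y78A peak. Both were present at 2853 genes, which is 49.8% of the wild type genes (interval 48.5 to 51.0). Among genes with wild type ENL and no Y78A peak, the strongest wild type peaks by the authors' fold were at SKAP2, which encodes a signalling adaptor, at 10.4-fold, and FNTA, which encodes a farnesyltransferase subunit, at 9.99-fold. C4BPB, the beta chain of a complement regulator, followed at 9.23-fold, then LARP7, a protein of the 7SK particle, at 9.18-fold. ZGRF1 shared the LARP7 peak on chromosome 4 (hg38, 112636962 to 112637543). GOLPH3L and HORMAD1 likewise shared a 9.17-fold peak on chromosome 1 (150697133 to 150697466). ICE1, a subunit of the little elongation complex, had a 9.17-fold peak on chromosome 5 (5422165 to 5422680). DCP1B, a factor of mRNA decapping, stood at 8.73-fold and CCNB1, which encodes cyclin B1, at 8.66-fold. All 10 of these genes also had an H3K9ac and an H3K9bhb peak at a gene end, and SKAP2 and ICE1 had an H3K9cr peak too.

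Genes with both ENL proteins included sites of similar or higher fold. The highest wild type fold, 15.9, was at LOC124905351 near the end of chromosome 3 (10064 to 10880), a place with a peak in all 5 lists. SPATC1L followed at 14.6-fold on chromosome 21 (46184411 to 46184821), again with a peak in all 5 lists. LRIF1, a heterochromatin-associated protein, stood at 10.6-fold, TMEM30A, a flippase subunit, at 10.5-fold, ARL6IP1 at 10.4-fold, and FBXL5, an iron-sensing F-box protein, at 10.3-fold. YPEL5 also reached 10.3-fold. DONSON, a replication factor, SON, a splicing factor, and RIMOC1 each had a 10.1-fold wild type peak. DONSON and SON shared that peak on chromosome 21 (33576657 to 33577142), and their strongest Y78A peaks lay at their other ends. Genes with a Y78A peak and no wild type peak numbered few, and the highest Y78A folds among them were 7.29 at FHIT, 6.41 at KPNA1, 6.32 at RBM45, 6.23 at ENOX2 and 6.19 at ANKRD54.

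The central question was whether ENL lies where H3K9bhb lies. With the lists as deposited, 6811 wild type ENL peaks were overlapped by H3K9bhb (59.8%, interval 58.9 to 60.7), and 74.7% of H3K9bhb peaks (interval 73.8 to 75.6) were overlapped by wild type ENL. H3K9ac, the longest list, overlapped 78.9% of wild type ENL peaks (interval 78.1 to 79.6), and H3K9cr overlapped 19.1% (interval 18.4 to 19.8). In the other direction, 28.6% of H3K9ac peaks and 56.7% of H3K9cr peaks were overlapped by wild type ENL. Random placement of these lists gave mean shares between 0.126% and 1.29% for the wild type peaks. At equal length the order changed: H3K9bhb overlapped 62.2% of wild type ENL peaks (interval 60.6 to 63.7), H3K9cr 34.3% (interval 32.8 to 35.8) and H3K9ac 31.3% (interval 29.8 to 32.8). The H3K9ac and H3K9cr lists also differ from the others in threshold and in peak-name form. Whether they came from the Flag-ENL cells is not given. The order of the marks cannot be told apart from these differences.

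Y78A peaks lay on each mark more often than wild type peaks did, with the lists as deposited. H3K9bhb overlapped 79.0% of Y78A peaks (interval 77.9 to 80.1), H3K9ac 85.8% (interval 84.8 to 86.7) and H3K9cr 31.3% (interval 30.1 to 32.5). The wild type share on H3K9bhb minus the Y78A share was −19.3 percentage points (interval −20.7 to −17.8). At equal length H3K9bhb overlapped 60.4% of Y78A peaks, and the difference was 1.74 points (interval −0.436 to 3.91). Such intervals take the lists as independent, although wild type and Y78A share many sites. Whether 0 lies inside therefore does not decide if the shares differ. For H3K9ac at equal length the wild type share was 2.65 points higher (interval 0.602 to 4.69), and for H3K9cr the difference was −3.09 points (interval −5.23 to −0.948).

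**Figure D1:**
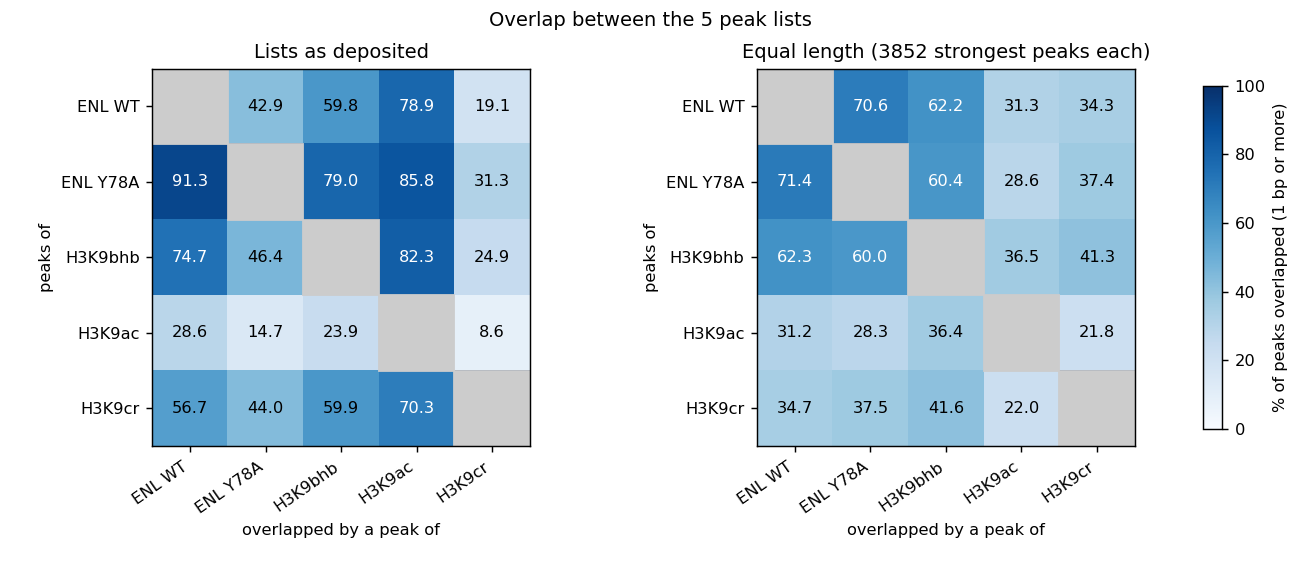
Percentage of the peaks of each list (rows) overlapped by at least 1 bp by a peak of another list (columns), with the lists as deposited (left) and with the 3852 strongest peaks of each (right). H3K9bhb overlapped 59.8% and H3K9ac 78.9% of wild type ENL peaks on the left, against 62.2% and 31.3% on the right.

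The marks were also compared with each other. H3K9bhb and H3K9cr peaks lay mostly within the larger H3K9ac list, with 82.3% of H3K9bhb peaks (interval 81.5 to 83.1) and 70.3% of H3K9cr peaks (interval 68.8 to 71.7) overlapped by H3K9ac. H3K9bhb overlapped 59.9% of H3K9cr peaks and 23.9% of H3K9ac peaks, and H3K9cr overlapped 24.9% of H3K9bhb peaks and 8.59% of H3K9ac peaks. At equal length 41.6% of H3K9cr peaks were overlapped by H3K9bhb and 22.04% by H3K9ac, while 36.5% of H3K9bhb peaks were overlapped by H3K9ac.

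Whether the wild type sites recovered in Y78A differed by mark was examined next. Wild type ENL peaks on H3K9bhb were recovered in Y78A in 60.1% of cases (4092 of 6811, interval 58.9 to 61.2), and those off H3K9bhb in 17.5% (800 of 4583, interval 16.4 to 18.6). The difference was 42.6 points (interval 41.0 to 44.2), and between 30.5 and 47.4 points within 4 equal groups of wild type peaks ranked by fold. Within 4 equal groups ranked by p, a grouping chosen after seeing the data, it was between 11.1 and 28.1 points for H3K9bhb, 5.26 and 16.7 for H3K9ac, and 10.8 and 21.5 for H3K9cr. Recovery was 48.4% on H3K9ac and 22.4% off it, and 72.3% on H3K9cr and 36.0% off it. The 1782 wild type peaks on all 3 marks were recovered in 80.2% of cases, and the 4236 on H3K9bhb and H3K9ac only in 55.0%. The 2815 on H3K9ac alone were recovered in 19.3%, the 651 on H3K9bhb alone in 40.2%, and the 1519 on none of the marks in 12.2%. Limiting each list to its strongest peaks reduced the H3K9ac difference from 26.0 to 4.93 points, and the H3K9bhb difference to 28.6 points. The H3K9cr difference, 36.3 points with the lists as deposited, fell too, although the H3K9cr list kept all its peaks. The cut removed a larger part of the H3K9ac list than of the H3K9bhb list. Wild type peaks whose only peak of a mark was removed then counted as off that mark. The falls therefore cannot be compared between marks.

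**Figure D2:**
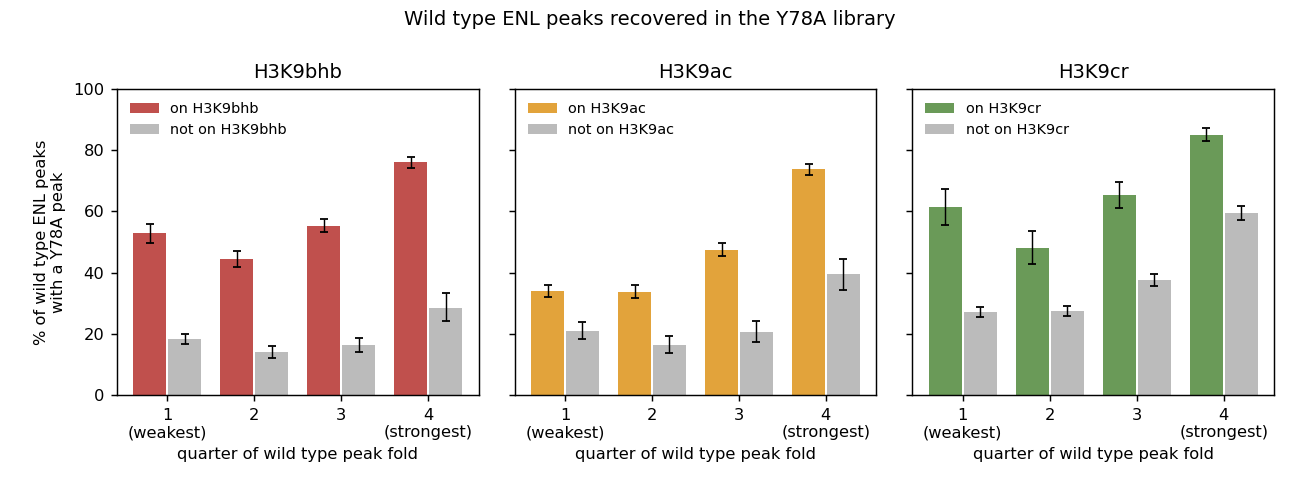
Percentage of wild type ENL peaks overlapped by a Y78A peak, in 4 equal groups ranked by the authors' wild type fold, for peaks on a mark (coloured bars) and off it (grey bars), with 95% Wilson intervals as error bars. Peaks on H3K9bhb were recovered more often than peaks off it in each group, 75.99% against 28.6% in the strongest.

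Since most ENL genes were acetylated, H3K9bhb was also compared within acetylated genes. Of the 5734 genes with wild type ENL at a gene end, 98.03% had H3K9ac there and 71.3% had H3K9bhb. Among the 11304 genes with H3K9ac, wild type ENL was present at 86.1% of the 4700 that also had H3K9bhb (interval 85.1 to 87.1) and at 23.8% of the 6604 that did not (interval 22.8 to 24.9). Y78A was present at 54.1% and 5.27% of the same genes. Within 4 equal groups ranked by H3K9ac fold the wild type difference stayed between 59.3 and 65.7 points. From the lowest group to the highest, wild type ENL fell from 93.03% to 77.6% of genes with H3K9bhb. At genes without H3K9bhb it fell from 28.9% to 18.3%. This fold may therefore not rank acetylation strength, and groups ranked by H3K9ac p were not run. The grouping cannot show whether acetylation strength accounts for the difference. With H3K9cr in place of H3K9bhb, wild type ENL was present at 93.6% of 880 genes, against 46.0% of the remaining 10424. Genes with H3K9bhb and no H3K9ac at a gene end were rare, and the highest H3K9bhb folds among them were at DIABLO, a mitochondrial activator of apoptosis, at 7.42, SRI and TEX48 at 7.24, OR2T1 at 5.89 and CDC42EP5 at 5.81. Genes with H3K9bhb and wild type ENL but no Y78A peak were led by LMAN1, a cargo receptor of the secretory pathway, with a 10.9-fold H3K9bhb peak on chromosome 18 (59359123 to 59359493). ICE1 followed at 9.39-fold, NMBR and VTA1, which share a peak, at 9.18-fold, and LMBRD1, a lysosomal cobalamin transport protein, at 8.67-fold.

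Liver and metabolic gene lists were then examined for gene-end peaks, and percentiles among 10000 random lists describe these libraries only. Cholesterol and lipid synthesis genes had wild type ENL at 21 of 30 and H3K9bhb at 18. All of these were among the 27 members with H3K9ac, at percentiles 99.7 and 99.6 among random lists of H3K9ac genes. HMGCS1 with a 7.76-fold wild type peak and STARD4 at 6.92-fold had no Y78A peak, while NSDHL at 7.19-fold did. Y78A had a peak at 10 genes of this list. Wild type ENL was at 18 of 30 liver transcription factor genes and Y78A at 13, all among the 23 members with H3K9ac. Their percentiles among H3K9ac genes were 99.64 and 99.9. TBX3 stood at 8.07-fold, ATF5 at 6.97-fold, NR1H3, the oxysterol receptor LXR alpha, at 5.78-fold and TCF7L2 at 5.14-fold. Each had a Y78A peak. H3K9bhb was at 10 genes of that list, all with H3K9ac, at percentile 56.98 among H3K9ac genes.

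Fasting and gluconeogenesis genes had wild type ENL at 15 of 30, H3K9bhb at 14 and Y78A at 8. Of the 22 members with H3K9ac, 14 had wild type ENL and 14 had H3K9bhb, at percentiles 89.8 and 97.9 among H3K9ac genes. PC, which encodes pyruvate carboxylase, had the strongest wild type peak at 9.21-fold, and SESN1 stood at 6.48-fold, both with Y78A. TAT, which encodes tyrosine aminotransferase, at 6.45-fold and INSIG2 at 6.30-fold had no Y78A peak. Among fatty acid oxidation and ketone body genes wild type ENL was at 15 of 40 and H3K9bhb at 9. Of the 28 members with H3K9ac, 14 had wild type ENL and 9 had H3K9bhb, at percentiles 50.7 and 15.6 among H3K9ac genes. The H3K9bhb number depended on the setting, with 14 in windows of 2500 bp, 16 with whole genes and 5 at equal length. Y78A was at 5 of those 15, a share of 33.3% (interval 15.2 to 58.3) at percentile 10.1 among random wild type genes. HADHA and HADHB, the subunits of the trifunctional protein, shared a 6.94-fold wild type peak that had a Y78A counterpart, whereas ETFDH at 6.82-fold and ACADM at 6.68-fold had none. Liver secreted protein genes carried H3K9ac at 27 of 40 members, wild type ENL at 11, H3K9bhb at 10 and Y78A at 7. F5, which encodes coagulation factor V, led with 8.17-fold and had no Y78A peak, followed by F2 (prothrombin) at 5.57-fold, AHSG at 4.67-fold and APOB at 4.61-fold. AFP and ALB had no gene-end peak in any of the 5 lists.

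Among random lists of H3K9ac genes, wild type ENL at 52 of the 76 ribosomal protein genes with H3K9ac lay at percentile 99.9. The percentile was 94.6 for elongation complexes (20 of 31 members with H3K9ac) and 87.4 for acylation enzymes and readers (17 of 28). It was 79.3 for cell cycle (22 of 39) and 17.9 for liver secreted proteins (11 of 27). Ribosomal protein genes had H3K9ac at 76 of 79 members, wild type ENL at 54, H3K9bhb at 32 and Y78A at 30, with RPL39 at 7.44-fold, RPL5 at 7.01-fold, RPS6 at 6.87-fold and RPS12 at 6.85-fold for wild type ENL. Of the 54 with wild type ENL, 27 had H3K9bhb, at percentile 0.045 among random wild type genes. The 32 genes with H3K9bhb, all among the 76 members with H3K9ac, lay at percentile 53.96 among H3K9ac genes, whose median was 32. For the whole list the percentile was 99.98 among all protein-coding genes. Cell cycle genes had wild type ENL at 22 of 40, H3K9bhb at 19 and Y78A at 13. CCNB1 and CDKN2C, at 7.26-fold, had no Y78A peak, unlike CDK2 at 7.80-fold and MCM3 at 7.57-fold. Elongation complex genes had wild type ENL at 20 of 33 and Y78A at 11, including CCNT2 at 7.70-fold and MLLT10 at 7.29-fold, while CTR9 at 7.42-fold had no Y78A peak. MLLT1, the gene of ENL itself, had H3K9ac and no ENL peak of either kind. H3K9bhb was at 13 genes of this list. Genes of lysine acylation enzymes and readers had wild type ENL at 18 of 30, H3K9bhb at 15 and Y78A at 9, led by the acetyltransferase genes EP300 at 8.68-fold, KAT6B at 8.16-fold, KAT7 at 7.85-fold and KAT6A at 6.97-fold.

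Genes bound by ENL in leukaemia had wild type ENL at 5 of 20 and Y78A and H3K9bhb at 3 each. The median of random lists was 6 for wild type ENL, and the 5 lay at percentile 37.99. As 5 of the 11 members with H3K9ac, they lay at percentile 39.9 among H3K9ac genes. They included PBX3 at 8.42-fold, JMJD1C at 4.74-fold, MYC at 4.10-fold and IGF2BP3 at 3.19-fold, and the strongest Y78A peak of MYC lay at its other end. The negative list, genes of other tissues, had no ENL or H3K9bhb peak at a gene end of any of 40 members (interval 0 to 8.76%), and H3K9ac at 4 (CD8A, MBP, PDX1 and SFTPC, named after their values were seen). With peaks anywhere in the gene counted, a setting chosen after seeing the data, 5 members had wild type ENL, 3 had Y78A and 4 had H3K9bhb. H3K9cr, present at 4.49% of protein-coding genes, was at 5 members in elongation complexes and 4 in cell cycle. Among random protein-coding genes these lay at percentiles 99.08 (median 1) and 93.6 (median 2). Among H3K9ac genes the percentiles were 94.2 for elongation complexes and 72.45 for cell cycle. H3K9cr was also at 3 members each in cholesterol synthesis and acylation enzymes, 2 each in ribosomal proteins and fatty acid oxidation, 1 each in fasting and leukaemia targets, and none in the remaining lists.

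**Figure D3:**
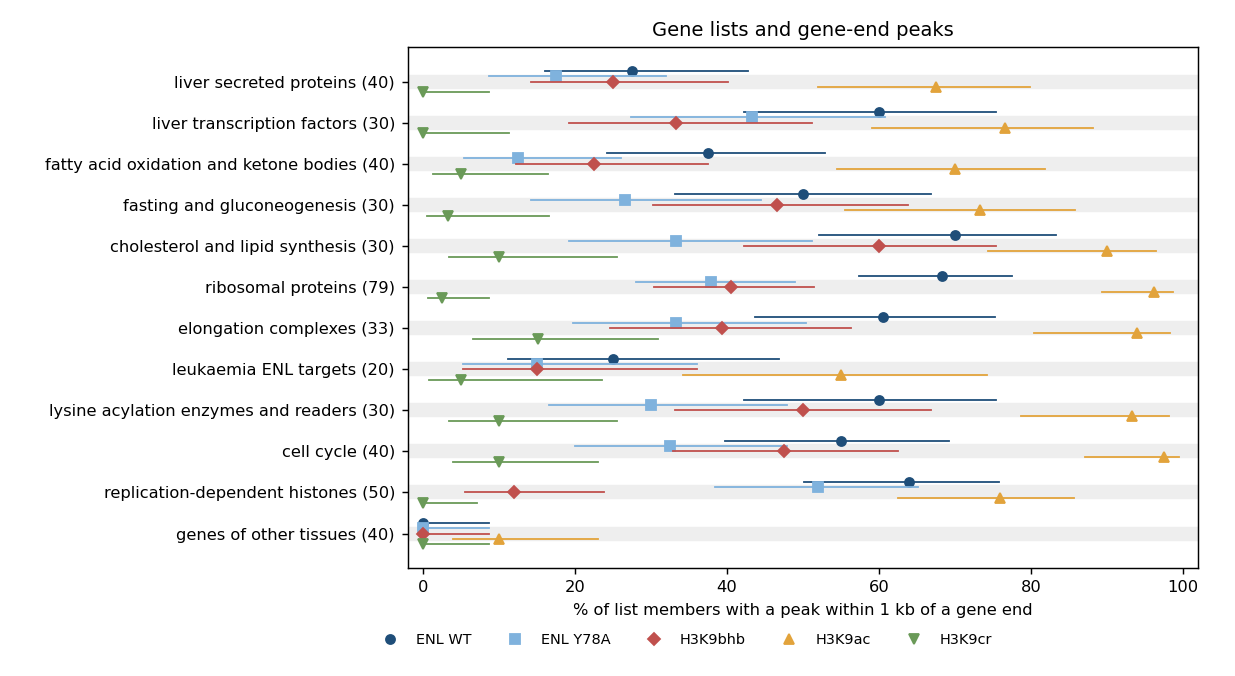
Percentage of the members of each gene list (members in parentheses) with a peak within 1 kb of a gene end in each library, with 95% Wilson intervals as horizontal lines. Wild type ENL was at 32 of 50 listed histone genes, all on chromosome 6, and 21 of 30 cholesterol and lipid synthesis genes. H3K9bhb was at 6 of 50 and 18 of 30 members.

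Replication-dependent histone genes of the list, all on chromosome 6, carried ENL and H3K9ac but few H3K9bhb peaks in the lists as deposited. Histone genes elsewhere were not in the list. On chromosome 6 (26017032 to 27893185), wild type ENL was at 32 of 50 genes and H3K9ac at 38, but H3K9bhb was at 6 and H3K9cr at 0. Y78A had a peak at 26 of the 32 wild type genes (81.2%, interval 64.7 to 91.1), at percentile 99.99 among random wild type genes. Counted by distinct peaks, Y78A recovered 21 of 31 (67.7%), at percentile 98.8 among sets matched on peak p and 85.7 among sets matched also on background, the latter chosen after seeing the data. The sets matched also on background, here and below, used coarser groups of p than those matched on p alone. With every list limited to its 3852 strongest peaks, wild type ENL was at 23 of the 50 genes and H3K9ac and H3K9bhb were at 0. The highest wild type folds were 5.98 at H2AC11 and H2BC11, which share a peak (27132431 to 27133404), 5.59 at H4C4 and 5.12 at H2AC15, and H4C4 had no Y78A peak. The 6 genes with H3K9bhb were H1-2, H1-4, H2AC13, H2BC13, H2BC3 and H2BC5, named after their values were seen. Neighbouring histone genes share peaks and near-identical sequence, so the 32 genes rest on 31 distinct wild type peaks and the 6 on 4 H3K9bhb peaks.

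**Figure D4:**
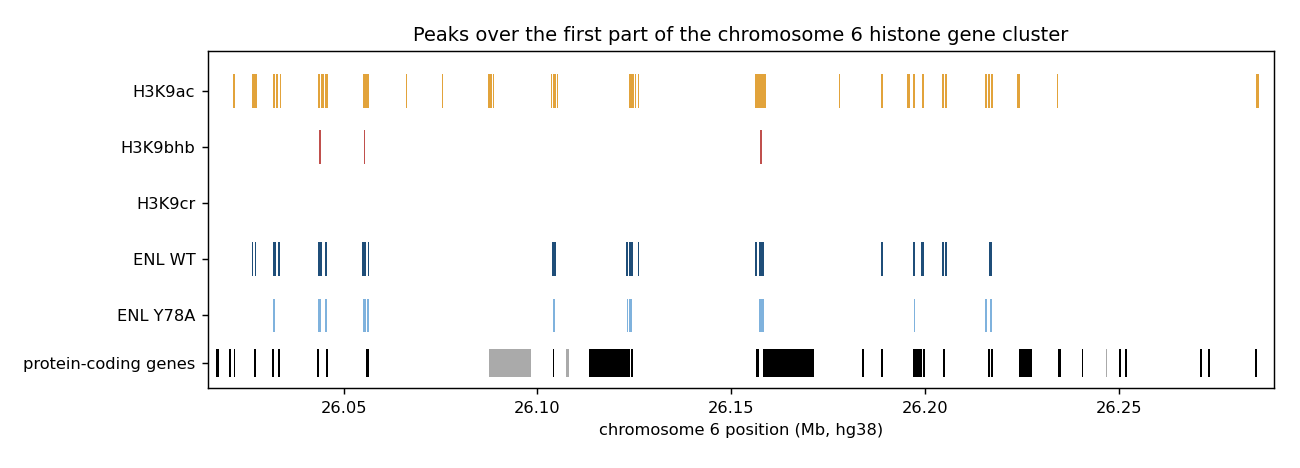
Peaks of the 5 lists over part of the chromosome 6 histone cluster (26.015 to 26.290 Mb, hg38), with protein-coding genes at the bottom, listed histone genes in black and other genes in grey; features under 350 bp are drawn 350 bp wide. The region held 34 H3K9ac, 21 wild type ENL, 12 Y78A, 3 H3K9bhb and 0 H3K9cr peaks.

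The strongest peaks of the libraries lay at the same few places away from genes. Chromosome 17 (25920049 to 25920425, 1374 kb from the nearest protein-coding gene end, that of WSB1) and chromosome 3 (93470293 to 93470865, 403 kb from PROS1) gave the highest wild type folds, 28.6 and 27.4. These places ranked first or second in all 5 lists, and the chromosome 3 summit held between 251 and 292 fragments in each. No such regions were filtered out here, so they count in the overlaps, also at equal length. The third strongest peak was on chromosome 13 (109424043 to 109424414 in wild type), 216 kb from MYO16, in both ENL lists and H3K9cr, and on chromosome 12 (133264811 to 133265348 in H3K9ac), 28.9 kb from ANHX, in H3K9ac and H3K9bhb. Of the 100 peaks with the highest fold in each list, between 84 and 96 had a peak in all 5 lists and between 1 and 5 were at a gene end. Over the whole lists, peaks shared by all 5 made up 26.3% of Y78A peaks, 12.5% of wild type ENL peaks, 15.6% of H3K9bhb peaks, 4.61% of H3K9ac peaks and 37.1% of H3K9cr peaks. Of these shared peaks, between 36.3% and 36.7% were at a gene end and between 21.5% and 21.7% lay more than 100 kb from any protein-coding gene.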

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

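The tests of call settings, common signal, shared reads, H3K9bhb depth and matching on background in this part were chosen after their results were seen. Peaks on contigs outside the standard chromosomes entered no comparison, and their numbers were above 0 in each library. There were 639 in wild type ENL, 375 in Y78A, 1720 in H3K9ac, 484 in H3K9bhb and 296 in H3K9cr, which is between 5.01% and 7.14% of each list. No explanation was tested for them.

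Y78A had 5422 peaks against 11394 for wild type ENL. Lower depth as the whole cause is argued against by thinning: after the wild type fragments and background were reduced to the Y78A background level with Poisson noise, 87.7% of wild type peaks still passed the lowest Y78A peak p, whereas 42.9% were recovered. A uniform loss of signal could not be settled. Y78A recovered 21 of 31 wild type peaks at histone genes, at percentile 98.8 among sets matched on peak p. The percentile was 85.7 among sets matched on p and local background. Those sets used coarser groups of p, so the fall cannot be put down to background, and the matchings do not decide. Lower depth, a lower yield of the Y78A library or of its protein, and weaker binding through the substituted pocket, may each account for the loss and stay open, since each group has 1 library.

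H3K9bhb overlapped 62.2% of wild type ENL peaks at equal length and H3K9ac 31.3%. Shared call settings were examined as a cause. H3K9ac, called with the same looser threshold as H3K9cr, overlapped 22.04% of H3K9cr peaks at equal length, against 41.6% for H3K9bhb. Among equal gene-end lists the shares were 22.96% and 46.3%, although H3K9ac peaks there were overlapped 22.6% by H3K9cr and 19.6% by H3K9bhb. The equal-length cut already removes the weaker peaks, which are most of the H3K9ac list, so this test cannot speak to the looser threshold. With every list cut at −log10 q of 5 instead, H3K9ac overlapped 69.6% of wild type ENL peaks and H3K9bhb 56.7%. Peak names also differ in form between the H3K9ac and H3K9cr lists and the others, and the cells of H3K9ac and H3K9cr are not fully described. A difference in cells or processing cannot be told apart from the difference between H3K9bhb and H3K9ac. A signal common to the wild type, Y78A and H3K9bhb libraries, such as open chromatin, stays open: the wild type share on H3K9bhb exceeded the Y78A share by 1.74 points (interval −0.436 to 3.91). That interval takes the lists as independent, although wild type and Y78A share many sites, so it does not decide. Reading of H3K9bhb by ENL, the question of the design, could give the same wild type overlap and was not separated from such a signal here. Y78A, with the pocket substituted, had a similar share on H3K9bhb, 60.4%. The overlap therefore does not show reading through that pocket.

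At the listed histone genes, all on chromosome 6, wild type ENL occupied 32 of 50 members and H3K9bhb 6. Reads shared between near-identical genes were considered as the reason for missing H3K9bhb peaks. Y78A had a peak at 20 of the 26 wild type genes without H3K9bhb (76.9%, interval 57.9 to 88.97). With Y78A at 26 of the 32 wild type genes and H3K9bhb at 6, fewer than 20 was not possible. The genes also share peaks, so the interval is too narrow, and shared reads stay open. The background level of H3K9bhb was 1.11 times that of Y78A, so it gave no sign of lower depth than Y78A. That level does not measure how well a mark was enriched and may depend on call settings. At a cut of −log10 q of 5, H3K9bhb was at 0 of the listed genes and wild type ENL at 31. H3K9bhb peaks missed near the calling limit therefore stay open. Of the 31 wild type peaks there, 4 were overlapped by H3K9bhb, against a mean of 20.7 in sets matched on peak p and 16.8 in sets matched also on background. A candidate explanation, as a hypothesis from these data alone, is that ENL occupies these chromosome 6 genes with little H3K9bhb. At equal length, though, H3K9ac was at 0 of them too and wild type ENL at 23. The hypothesis needs replicate libraries and does not cover histone genes elsewhere.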

How the results depend on the processing

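Settings restricted by gene ends, by distance from genes or by whole genes, and the cut at −log10 q of 2, were chosen after seeing the data, and the rest were fixed before the data were examined. Of the recomputed values, 291 stayed within the 95% interval of the main value, or within 1.5 times for a count, 203 moved further and 4 changed sign. Those 4 were wild type minus Y78A shares on a mark, negative with the lists as deposited for all 3 marks: the share on H3K9bhb reversed in both equal-length settings, that on H3K9ac at equal length and that on H3K9cr among equal gene-end lists. Of these, only the H3K9ac reversal had an interval that left out 0, and these intervals take the wild type and Y78A lists as independent although they share sites. Recovery in Y78A was higher on each mark than off it, and wild type ENL was more frequent at H3K9ac genes with H3K9bhb or H3K9cr, in every setting run, though the H3K9ac gain among equal gene-end lists had an interval that included 0. The order of the marks on ENL peaks did change. H3K9ac overlapped the most wild type and Y78A peaks with the lists as deposited and under each overlap rule, the cut at −log10 q of 5, the cut at 2 and both restrictions by position, whereas H3K9bhb overlapped the most at equal length, with or without the restriction to gene ends. A shorter or stricter list holds fewer peaks by construction, and so has fewer genes. For the other moves the cause was not tested. Read depth is unknown, so a peak missing from a list was not shown to be absent from the cells. The alternative with the 5′ ends of every protein-coding transcript was not run, since the annotation used has no strand or transcripts. No paired analysis was possible because each group has 1 library.

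The following values moved or reversed, with q5 standing for the cut at −log10 q of 5 in each list. By summit position, wild type ENL peaks were overlapped 39.7% by Y78A, 55.8% by H3K9bhb, 73.96% by H3K9ac and 16.9% by H3K9cr. By summit position, Y78A peaks were overlapped 89.1% by wild type, 75.3% by H3K9bhb, 81.6% by H3K9ac and 28.3% by H3K9cr. By summit position, H3K9bhb peaks were overlapped 70.9% by wild type, 78.1% by H3K9ac and 22.1% by H3K9cr. By summit position, H3K9ac peaks were overlapped 22.5% by wild type, 18.4% by H3K9bhb and 6.92% by H3K9cr. By summit position, H3K9cr peaks were overlapped 53.5% by wild type, 56.1% by H3K9bhb and 66.7% by H3K9ac. By summit position, the gain in recovery was 22.6 points on H3K9ac. By the shorter-peak rule, wild type ENL peaks were overlapped 58.5% by H3K9bhb and 75.97% by H3K9ac. By the shorter-peak rule, Y78A peaks were overlapped 89.9% by wild type, 77.3% by H3K9bhb and 82.8% by H3K9ac. By the shorter-peak rule, H3K9bhb peaks were overlapped 72.97% by wild type and 79.8% by H3K9ac. By the shorter-peak rule, H3K9ac peaks were overlapped 27.1% by wild type and 23.02% by H3K9bhb. By the shorter-peak rule, H3K9cr peaks were overlapped 54.96% by wild type, 57.9% by H3K9bhb and 68.2% by H3K9ac. Within 500 bp, wild type ENL peaks were overlapped 44.5% by Y78A, 61.6% by H3K9bhb, 81.1% by H3K9ac and 19.8% by H3K9cr. Within 500 bp, Y78A peaks were overlapped 92.3% by wild type, 80.8% by H3K9bhb and 87.9% by H3K9ac. Within 500 bp, H3K9bhb peaks were overlapped 75.96% by wild type, 83.96% by H3K9ac and 25.96% by H3K9cr. Within 500 bp, H3K9ac peaks were overlapped 32.3% by wild type, 26.8% by H3K9bhb and 9.31% by H3K9cr. Within 500 bp, H3K9cr peaks were overlapped 58.4% by wild type, 61.5% by H3K9bhb and 72.1% by H3K9ac.

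At q5, wild type ENL peaks were overlapped 56.7% by H3K9bhb, 69.6% by H3K9ac and 12.2% by H3K9cr. At q5, Y78A peaks were overlapped 75.8% by H3K9bhb, 77.1% by H3K9ac and 22.5% by H3K9cr. At q5, H3K9bhb peaks were overlapped 76.5% by wild type, 76.3% by H3K9ac and 17.6% by H3K9cr. At q5, H3K9ac peaks were overlapped 34.5% by wild type, 28.1% by H3K9bhb and 6.60% by H3K9cr. At q5, H3K9cr peaks were overlapped 60.7% by wild type, 64.99% by H3K9bhb and 65.7% by H3K9ac. At q5, the gain in recovery was 40.6 points on H3K9bhb, 20.97 points on H3K9ac and 41.8 points on H3K9cr. The wild type minus Y78A share moved to −10.3 points on H3K9cr (interval −11.8 to −8.94), at q5. At q5, peaks numbered 18480 for H3K9ac and 1848 for H3K9cr. At q5, gene-end shares were 44.4% for wild type, 49.4% for H3K9ac, 45.1% for H3K9bhb and 13.2% for H3K9cr. At q5, genes with a gene-end peak numbered 302 for H3K9cr. At q5, 46.7% of wild type genes had a Y78A peak. At q5, the gain in ENL at H3K9ac genes was 50.6 points with H3K9cr. At q5, list members with a H3K9bhb peak numbered 6 for liver secreted proteins and 0 for replication-dependent histones. At equal length, wild type ENL peaks were overlapped 70.6% by Y78A, 62.2% by H3K9bhb, 31.3% by H3K9ac and 34.3% by H3K9cr. At equal length, Y78A peaks were overlapped 71.4% by wild type, 60.4% by H3K9bhb, 28.6% by H3K9ac and 37.4% by H3K9cr. At equal length, H3K9bhb peaks were overlapped 62.3% by wild type, 36.5% by H3K9ac and 41.3% by H3K9cr. At equal length, H3K9ac peaks were overlapped 31.2% by wild type, 36.4% by H3K9bhb and 21.8% by H3K9cr. At equal length, H3K9cr peaks were overlapped 34.7% by wild type, 41.6% by H3K9bhb and 22.04% by H3K9ac. At equal length, the gain in recovery was 28.6 points on H3K9bhb, 4.93 points on H3K9ac and 23.7 points on H3K9cr. The wild type minus Y78A share reversed to 1.74 points on H3K9bhb (interval −0.436 to 3.91) and 2.65 points on H3K9ac (interval 0.602 to 4.69), and moved to −3.09 points on H3K9cr (interval −5.23 to −0.948), at equal length. At equal length, genes with a gene-end peak numbered 2375 for wild type, 3389 for H3K9ac and 2284 for H3K9bhb. At equal length, 70.3% of wild type genes had a Y78A peak. At equal length, the gain in ENL at H3K9ac genes was 51.3 points with H3K9bhb and 52.1 points with H3K9cr. At equal length, list members with a wild type peak numbered 5 for liver secreted proteins, 6 for liver transcription factors, 7 for fatty acid oxidation and ketone bodies, 9 for fasting and gluconeogenesis, 9 for cholesterol and lipid synthesis, 27 for ribosomal proteins, 10 for elongation complexes, 2 for leukaemia ENL targets, 11 for lysine acylation enzymes and readers and 14 for cell cycle. At equal length, list members with a H3K9bhb peak numbered 1 for liver secreted proteins, 5 for liver transcription factors, 5 for fatty acid oxidation and ketone bodies, 7 for fasting and gluconeogenesis, 7 for cholesterol and lipid synthesis, 11 for ribosomal proteins, 8 for elongation complexes, 8 for lysine acylation enzymes and readers, 11 for cell cycle and 0 for replication-dependent histones.

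Among gene-end peaks, wild type ENL peaks were overlapped 46.3% by Y78A, 66.6% by H3K9bhb, 92.6% by H3K9ac and 13.3% by H3K9cr. Among gene-end peaks, Y78A peaks were overlapped 95.5% by wild type, 85.1% by H3K9bhb, 93.6% by H3K9ac and 22.1% by H3K9cr. Among gene-end peaks, H3K9bhb peaks were overlapped 83.3% by wild type, 95.01% by H3K9ac and 16.4% by H3K9cr. Among gene-end peaks, H3K9ac peaks were overlapped 39.3% by wild type, 32.4% by H3K9bhb and 6.03% by H3K9cr. Among gene-end peaks, H3K9cr peaks were overlapped 89.1% by wild type, 89.3% by H3K9bhb and 95.2% by H3K9ac. Among gene-end peaks, the gain in recovery was 13.999 points on H3K9ac and 40.5 points on H3K9cr. The wild type minus Y78A share moved to −1.001 points on H3K9ac (interval −2.19 to 0.262) and −8.83 points on H3K9cr (interval −10.8 to −6.94), among gene-end peaks. Without far peaks, wild type ENL peaks were overlapped 41.6% by Y78A, 80.5% by H3K9ac and 16.3% by H3K9cr. Without far peaks, Y78A peaks were overlapped 93.2% by wild type, 88.4% by H3K9ac and 26.7% by H3K9cr. Without far peaks, H3K9bhb peaks were overlapped 84.4% by H3K9ac and 21.5% by H3K9cr. Without far peaks, H3K9ac peaks were overlapped 27.9% by wild type, 23.2% by H3K9bhb and 7.32% by H3K9cr. Without far peaks, H3K9cr peaks were overlapped 59.6% by wild type, 62.8% by H3K9bhb and 77.1% by H3K9ac. The wild type minus Y78A share moved to −10.3 points on H3K9cr (interval −11.8 to −8.90), without far peaks. Among equal gene-end lists, wild type ENL peaks were overlapped 66.03% by Y78A, 53.5% by H3K9bhb, 10.5% by H3K9ac and 41.03% by H3K9cr. Among equal gene-end lists, Y78A peaks were overlapped 66.2% by wild type, 50.8% by H3K9bhb, 10.7% by H3K9ac and 39.3% by H3K9cr. Among equal gene-end lists, H3K9bhb peaks were overlapped 53.7% by wild type, 19.7% by H3K9ac and 45.8% by H3K9cr. Among equal gene-end lists, H3K9ac peaks were overlapped 10.5% by wild type, 19.6% by H3K9bhb and 22.6% by H3K9cr. Among equal gene-end lists, H3K9cr peaks were overlapped 41.8% by wild type, 46.3% by H3K9bhb and 22.96% by H3K9ac. Among equal gene-end lists, the gain in recovery was 21.8 points on H3K9bhb, 3.13 points on H3K9ac and 19.98 points on H3K9cr. The wild type minus Y78A share reversed to 2.72 points on H3K9bhb (interval −2.38 to 7.80) and 1.77 points on H3K9cr (interval −3.24 to 6.76), and moved to −0.272 points on H3K9ac (interval −3.44 to 2.89), among equal gene-end lists.

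With the 500 bp window, gene-end shares were 37.9% for wild type, 39.5% for Y78A, 26.2% for H3K9ac, 38.7% for H3K9bhb and 15.9% for H3K9cr. With the 500 bp window, the gain in ENL at H3K9ac genes was 50.1 points with H3K9cr. With the 500 bp window, list members with a wild type peak numbered 3 for leukaemia ENL targets. With the 500 bp window, list members with a Y78A peak numbered 4 for liver secreted proteins and 1 for leukaemia ENL targets. With the 2500 bp window, gene-end shares were 48.8% for wild type, 50.02% for Y78A, 46.6% for H3K9ac, 47.9% for H3K9bhb and 23.4% for H3K9cr. With the 2500 bp window, the gain in ENL at H3K9ac genes was 43.2 points with H3K9cr. With the 2500 bp window, list members with a H3K9bhb peak numbered 14 for fatty acid oxidation and ketone bodies. With whole genes, list members with a wild type peak numbered 5 for genes of other tissues. With whole genes, list members with a Y78A peak numbered 16 for cholesterol and lipid synthesis, 5 for leukaemia ENL targets and 3 for genes of other tissues. With whole genes, list members with a H3K9bhb peak numbered 16 for fatty acid oxidation and ketone bodies, 5 for leukaemia ENL targets and 4 for genes of other tissues.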

Other observations

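The tests behind these values were chosen after the data were seen. ENL at genes of small RNAs was compared between wild type and Y78A. Of 443 tRNA genes, 80 had a wild type ENL peak within 1 kb and 20 of these had a Y78A peak (interval of the share 16.8% to 35.5%), against 49.8% of protein-coding genes with wild type ENL. H3K9bhb was present at 48 of the 80 tRNA genes. Of 154 snRNA genes, 45 had wild type ENL and 28 had Y78A. Away from protein-coding gene ends by more than 2 kb, 42 of 368 tRNA genes had wild type ENL and 10 had Y78A (23.8% recovered, interval 13.5 to 38.5), while 22 of 38 snRNA genes were recovered (57.9%, interval 42.2 to 72.1). These shares are not matched on peak strength. Counted by distinct wild type peaks, Y78A recovered 19 of 64 at tRNA genes, at percentile 37.9 among sets matched on peak p and 22.9 among sets matched also on background, so the low tRNA share was near that of other peaks of the same p. For snRNA genes 28 of 46 peaks were recovered, at percentiles 98.98 and 95.1, and away from gene ends 23 of 39, at percentiles 93.7 and 81.8. Clustered tRNA genes can share a peak, so these genes are not independent.

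H3K9ac summits sat further from gene ends than those of ENL. The median distance of a gene-end summit to the nearest protein-coding gene end was 152 bp for wild type ENL, 159 bp for Y78A, 150 bp for H3K9bhb, 207.5 bp for H3K9cr and 230 bp for H3K9ac. Among H3K9ac genes without H3K9bhb, wild type ENL was present at 28.9% in the lowest of 4 equal groups ranked by H3K9ac fold and at 18.3% in the highest. Peaks found in 1 list only were seldom at gene ends for H3K9cr (2.39% of 753), Y78A (4.27% of 117) and H3K9bhb (5% of 660). The share was 11.6% of 1333 for wild type ENL and highest for H3K9ac, with 30.96% of 20418.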
